A study of Mus musculus with 6 samples.

How the data were processed

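Gene expression was measured in bladders of mouse embryos at embryonic day 14.5. Per the labels, 2 genotypes were compared with 3 samples each, and each sample was a pool of 2 whole bladders. In the Klf5-deleted embryos the gene Klf5, which codes for a zinc-finger transcription factor of epithelia, carried a deletion on both alleles. The controls had intact Klf5 alleles and carried ShhGfpCre, an allele that makes the Cre recombinase in cells that express Shh, such as the epithelium lining the bladder. The Klf5 deletion was taken to lie only in epithelium that expresses Shh, so that other cells of the bladder keep the gene. The labels name the tissue both as urothelium and as whole bladder, and the extraction protocol speaks of whole bladders, so the RNA was taken to include muscle, connective tissue, vessels, blood and nerve. Total RNA was hybridised to Affymetrix Mouse Gene ST arrays, 1 array per sample.

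The authors deposited log2 expression values, 1 per array feature and array, made with RMA (robust multi-array averaging, which corrects background, normalizes arrays by quantiles and summarises probes), per the submitters' processing notes. The version of RMA, the genome build and the probe annotation are not given in the sources used here. That the scale is log2 was inferred from the values, which ran from 3.24 to 14.6 with nearly equal distributions on the 6 arrays. The array medians over all features lay between 7.68 and 7.80. Scanner files were not used here, so no feature could be called above or below background, and RMA is known to compress the differences of dim features. The number of arrays limits the precision. The p-values measure the spread between pools; the labels do not say whether pools of a genotype came from separate litters.

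The table held 35557 features. The annotation table gave 21789 features a single gene symbol and 1621 several, and 12147 were unnamed here. Only features with a single symbol were tested. For the 999 genes with more than 1 feature, the feature with the highest mean over all 6 arrays stood for the gene, which left 19938 genes. Of these, 19856 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, no symbol needed an update, and 82 kept the symbol of the array annotation. No coordinates are printed because no build is stated for the deposited values.

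Expression was compared as Klf5-deleted minus control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), with Benjamini-Hochberg adjustment over the 19938 genes and a threshold of 0.05 on the adjusted p. Differences are on the log2 scale, with standard errors (SE) from limma, and group values are means ± SD over 3 arrays. A second count added a change of at least 2-fold. Exact permutation of 3 arrays against 3 cannot give a p under 0.1, so single genes rest on limma's model, which shares the spread across genes.

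Before the data were examined, 30 gene lists with 509 members were fixed, of which 476 were measured, 1 of them under an older symbol. They covered urothelial and epithelial genes, pathways, the other cell types of a bladder or its surroundings, and signs of RNA quality. The 29 lists other than the sex-linked genes were tested with limma's camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. Camera asks whether the members differ more in one direction than the other genes. Camera with an estimated correlation and limma's fry were run beside it. The genes named in the text were chosen by a rule fixed at the same time. It took Klf5, the 12 largest falls and the 12 largest rises among genes past the threshold whose groups did not overlap, up to 4 members per list, and the genes Upk1a, Upk1b, Upk2, Upk3a, Upk3b, Pparg, Grhl3, Elf3, Ovol1, Shh, Acta2 and Myh11, which made 95 genes. The placental, granzyme, yolk sac and Y-linked genes, the ceramide and trafficking genes, B2m and Pgk1, and the members of symbol families that the text names outside this rule were chosen after their values were seen.

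The procedure was tested on simulated data with 200 changed genes among 19938, in 20 runs of 3 against 3 arrays. Values were drawn independently for each gene and array from normal distributions with the spread that limma had fitted. Genes did not vary together and arrays had no shared shifts, so the rates describe that model and may not hold for the real arrays. It recovered 97.4% of genes changed 2-fold and 67.3% of genes changed 1.41-fold, 5.71% of calls were unchanged genes, and no call had the wrong sign. A list shifted by -0.3 was called in 20 of 20 runs. With no change simulated, camera with the preset correlation called 8 of 580 list tests after adjustment, and 6 of 20 runs held at least 1 such call. That share of runs is larger than the adjusted p threshold, so camera with the preset correlation missed its level in the simulation. The rate of such calls on lists whose members vary together, such as the erythroid list with an estimated correlation of 0.867, was not tested.

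The alternatives left out each array in turn, used the replicate number as a block, changed the variance model, the array weights, the normalization, the filter on dim genes, the choice among features of a gene and the thresholds, and changed the list test. A setting without control 2 and Klf5-deleted 2 was added after seeing the data. Marker lists of trophoblast, decidua and yolk sac, and lists of ceramide metabolism and vesicle trafficking, were also put together after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.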

Results

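RNA of 6 pools of mouse embryonic bladders was measured on arrays, 3 pools from embryos with Klf5 deleted and 3 from controls, to learn which transcripts of the developing bladder depend on Klf5. The study's title places the question in the maturation of the urothelium, the epithelium that lines the bladder. Arrays of the Klf5-deleted group correlated with each other at Pearson's r of 0.994 to 0.996 across genes, and arrays of the control group at 0.987 to 0.996. The lowest of these correlations joined control 1 and control 2. Genes are not independent replicates, so these values only describe the arrays. No array repeated another: at most 20 of 19938 genes held exactly equal values in a pair, and at least 41 genes differed 2-fold or more within each pair of the same group.

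Klf5 itself was lower in the Klf5-deleted bladders. Its log2 level was 10.23 ± 0.11 (SD, n = 3) against 10.82 ± 0.17 (SD, n = 3) in controls. The difference was -0.59 (95% confidence interval -0.83 to -0.34), with an adjusted p of 0.0381 by limma. The 3 Klf5-deleted arrays read 10.12, 10.34 and 10.23, and the 3 control arrays 10.84, 10.63 and 10.97, so the groups did not overlap. Cells that do not express Shh were taken to keep the gene in these whole bladders, and which part of Klf5 the array feature covers was not analysed here. The call did not hold in every setting. Centring each array on its housekeeping genes gave a difference of -0.37 with an adjusted p of 0.0651 by limma. Here and below this centring rests on a single gene per array, B2m or Pgk1, and moves the difference of every gene by the same amount. Leaving out any array other than control 2 gave an adjusted p by limma of 0.0847 to 0.156, with differences of -0.64 to -0.51; without control 2 the difference was -0.68 with an adjusted p of 0.0167.

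In the comparison of all genes, most transcripts past the threshold were lower in the Klf5-deleted bladders. limma placed 395 of 19938 genes past an adjusted p of 0.05, of which 318 fell and 77 rose. At least 2-fold changes numbered 107, with 105 falls and 2 rises. The groups did not overlap for any of the 395 genes; over all genes 20.5% did not overlap, where chance gives 10%. The count fell to 141 without Klf5-deleted 1, 172 without Klf5-deleted 2, 253 without Klf5-deleted 3, 165 without control 1 and 261 without control 3, and was 349 without control 2, an array with abundant placental transcripts described further on. Centring each array on its housekeeping genes moved the split to 261 falls and 1372 rises and the median of all genes to 0.202, from -0.0099. The 395 genes all kept their sign, which a shift of this size could not have changed.

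The 12 largest falls began with Sprr1a, a component of the cornified envelope of squamous epithelia, which was 21.8-fold lower (log2 difference -4.45, SE 0.30, adjusted p = 0.0012 by limma). Clca1, a secreted regulator of chloride channels, was 11.4-fold lower, and the uroplakin gene Upk2 was 9.13-fold lower. Tmem45b fell by 3.13 on the log2 scale and Plet1, a surface protein of epithelial progenitors, fell by 2.73. Psca, a surface antigen of urothelium and prostate, fell by 2.82 and Upk1a fell by 2.72. Mal, a membrane protein of apical transport, fell by 2.69, and Snx31, a sorting nexin of urothelium, fell by 2.58. The dehydrogenase genes Aldh1a7, Aldh3b2 and Adh1 were also lower: Aldh1a7 fell by 3.02, Aldh3b2 fell by 2.69 and Adh1 fell by 2.58. Aldh1a7 and Aldh3b2 have close paralogs, whose transcripts the array may not separate.

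The 12 largest rises were smaller. Onecut2, a homeobox transcription factor, was 2.40-fold higher (log2 difference 1.27, SE 0.15, adjusted p = 0.00909 by limma). Hmcn1, a large extracellular matrix protein, was 2.13-fold higher (1.09, SE 0.19, adjusted p = 0.035 by limma); the gene has 77 features on the array, and their mean differed by 0.77. The retinoid X receptor gene Rxrg rose by 1.00 and the sialyltransferase gene St6gal2 by 0.91. Crhbp, which codes for a binding protein of corticotropin-releasing hormone, rose by 0.87, and the somatostatin receptor gene Sstr1 by 0.84. Cntn6 and Edil3, which code for an adhesion and a matrix protein, rose by 0.86 and 0.74. The transcription regulators Zfp521, Eya4 and Sox11 rose by 0.77, 0.76 and 0.71, and the cytokine gene Tnfsf13b rose by 0.74.

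**Figure D1:**
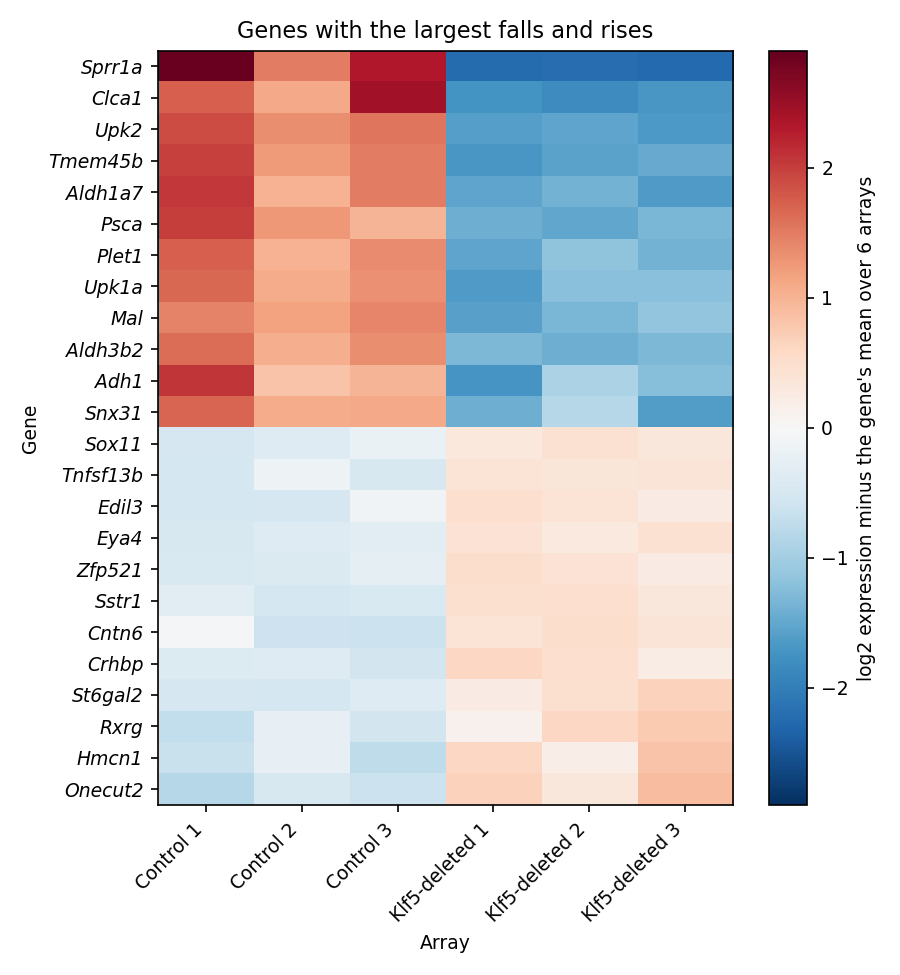
Heat map of the 12 largest falls and 12 largest rises among genes past an adjusted p of 0.05, as log2 expression minus the mean of the gene over 6 arrays, for 3 control and 3 Klf5-deleted arrays. The falls, up to -4.45 for Sprr1a, exceed the rises, up to 1.27 for Onecut2, and the groups do not overlap for any of these genes.

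Uroplakins, the membrane proteins of the plaques on the urothelial surface, and other products of differentiated urothelium fell together. Of 19 measured members of this list, 14 fell, none rose and 5 did not pass; adjusted over the list alone, 17 fell. The median log2 difference was -1.52, or -1.31 with arrays centred on housekeeping genes. Upk2 was 8.30 ± 0.07 (SD, n = 3) in Klf5-deleted and 11.49 ± 0.28 (SD, n = 3) in control bladders. Upk1b fell by 2.35 (SE 0.15) and Upk3a fell by 1.98 (SE 0.18), each with an adjusted p under the threshold by limma. Upk3b differed by -0.32 (SE 0.13, adjusted p = 0.329 by limma) and did not pass. Which cells of the whole bladder gave its reading was not tested. Camera with the preset correlation gave the list an adjusted p of 1.38e-28, and an adjusted p of 0.0544 with an estimated correlation.

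**Figure D2:**
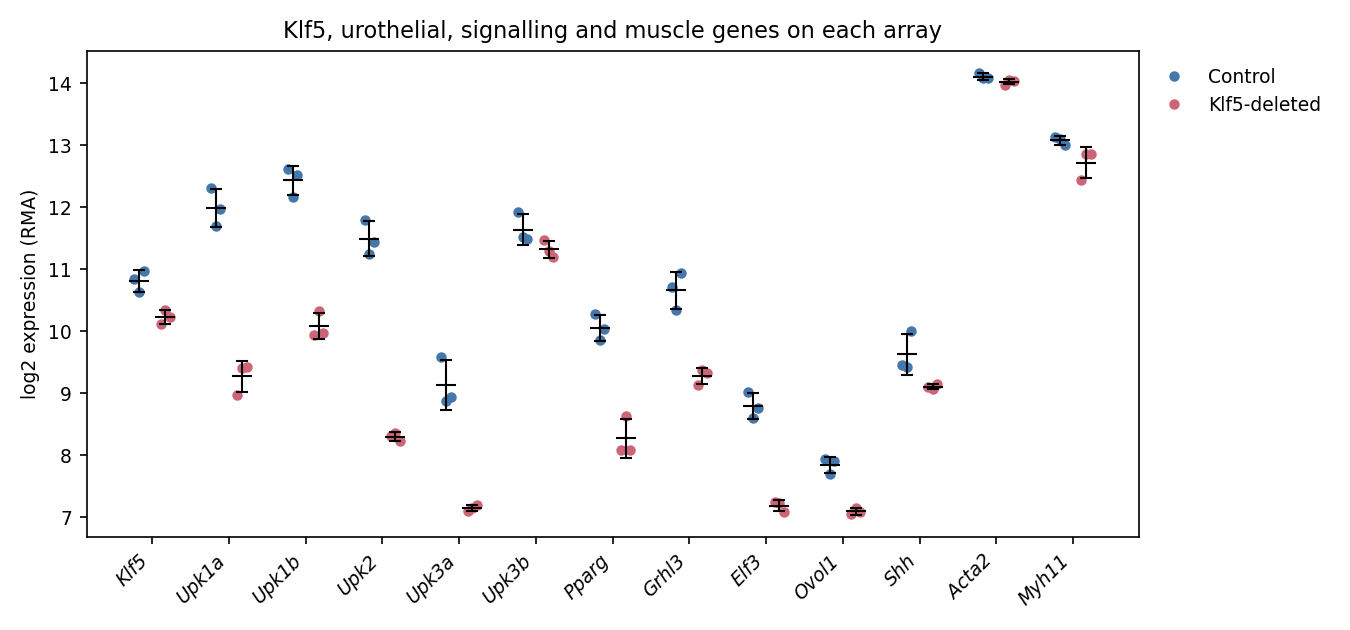
Log2 expression (RMA) of Klf5 and 12 genes fixed before the data were examined, on each of 3 control and 3 Klf5-deleted arrays; points are arrays, horizontal marks the group means and bars the SD. All genes shown, Acta2 and Myh11 included, lie lower in every Klf5-deleted array than in every control array. Upk1a, Upk1b, Upk2 and Upk3a pass the threshold, while Acta2 and Myh11 differ by -0.08 and -0.36 without passing it.

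Among transcription and splicing regulators of epithelia, the genes past the threshold were all lower in the Klf5-deleted bladders. Of 28 measured members 11 fell, none rose and 17 did not pass; adjusted over the list alone, 17 fell and 1 rose. Ehf and Elf3, ETS factors of epithelia, fell by 1.87 and 1.60. Pparg, a nuclear receptor that drives urothelial differentiation and lipid storage, fell by 1.78 (SE 0.17, adjusted p = 0.0037 by limma). Grhl3, a factor of the epithelial barrier, fell by 1.38 (SE 0.15), and Ovol1 fell by 0.75 (SE 0.08). The list median was -0.404, or -0.192 with arrays centred on housekeeping genes. The number of falls was 7 without Klf5-deleted 1 or without control 1. Camera gave an adjusted p of 1.06e-10, and an adjusted p of 0.0544 with an estimated correlation.

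In the lists of cell junctions and of epithelia in general, all genes past the threshold fell. In the general epithelial list 10 of 18 measured members fell and none rose, also when adjusted over the list alone, with a median of -0.709. Prom2 fell by 1.95, the protease inhibitor gene Spint1 fell by 1.88 and the trafficking GTPase gene Rab25 fell by 1.66. Cdh1, which codes for E-cadherin, was 2.82-fold lower. Of 16 desmosome and gap junction genes 4 fell, or 9 adjusted over the list alone: Ppl fell by 1.17, Perp fell by 1.13, Evpl fell by 0.54 and Jup fell by 0.43. Of 21 tight junction genes 3 fell, or 11 adjusted over the list alone: Cldn4 fell by 1.10, Tjp3 fell by 0.74 and Cldn23 fell by 0.68. The other 12 desmosome and gap junction genes and 18 tight junction genes did not pass, and 8 tight junction genes were higher. The medians were -0.333 for desmosomes and -0.276 for tight junctions; with arrays centred on housekeeping genes they were -0.497 for the general list, -0.121 and -0.0643. Only 1 tight junction gene fell past the threshold without Klf5-deleted 1, Klf5-deleted 3, control 1 or control 3. Camera's adjusted p was 5.06e-15 for the general list, 2.86e-08 for desmosomes and 9.76e-05 for tight junctions. With an estimated correlation the adjusted p was 0.0901, 0.0544 and 0.409.

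Among 22 basal and squamous genes 5 fell and none rose, or 9 falls adjusted over the list alone. Besides Sprr1a, the cornified envelope gene Ivl fell by 2.13, and the keratin genes Krt4 and Krt15 fell by 1.77 and 1.43. Of 15 epithelial channels and transporters 2 fell, or 7 adjusted over the list alone: Scnn1g, a subunit of the epithelial sodium channel, fell by 1.86 and the water and glycerol channel gene Aqp3 was 2.66-fold lower. The medians were -0.33 and -0.303, or -0.118 and -0.091 with arrays centred on housekeeping genes and -0.209 and -0.276 without control 2. Camera's adjusted p was 1.06e-10 for the basal and 1.47e-06 for the channel list, and with an estimated correlation the adjusted p was 0.0901 and 0.0544.

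**Figure D3:**
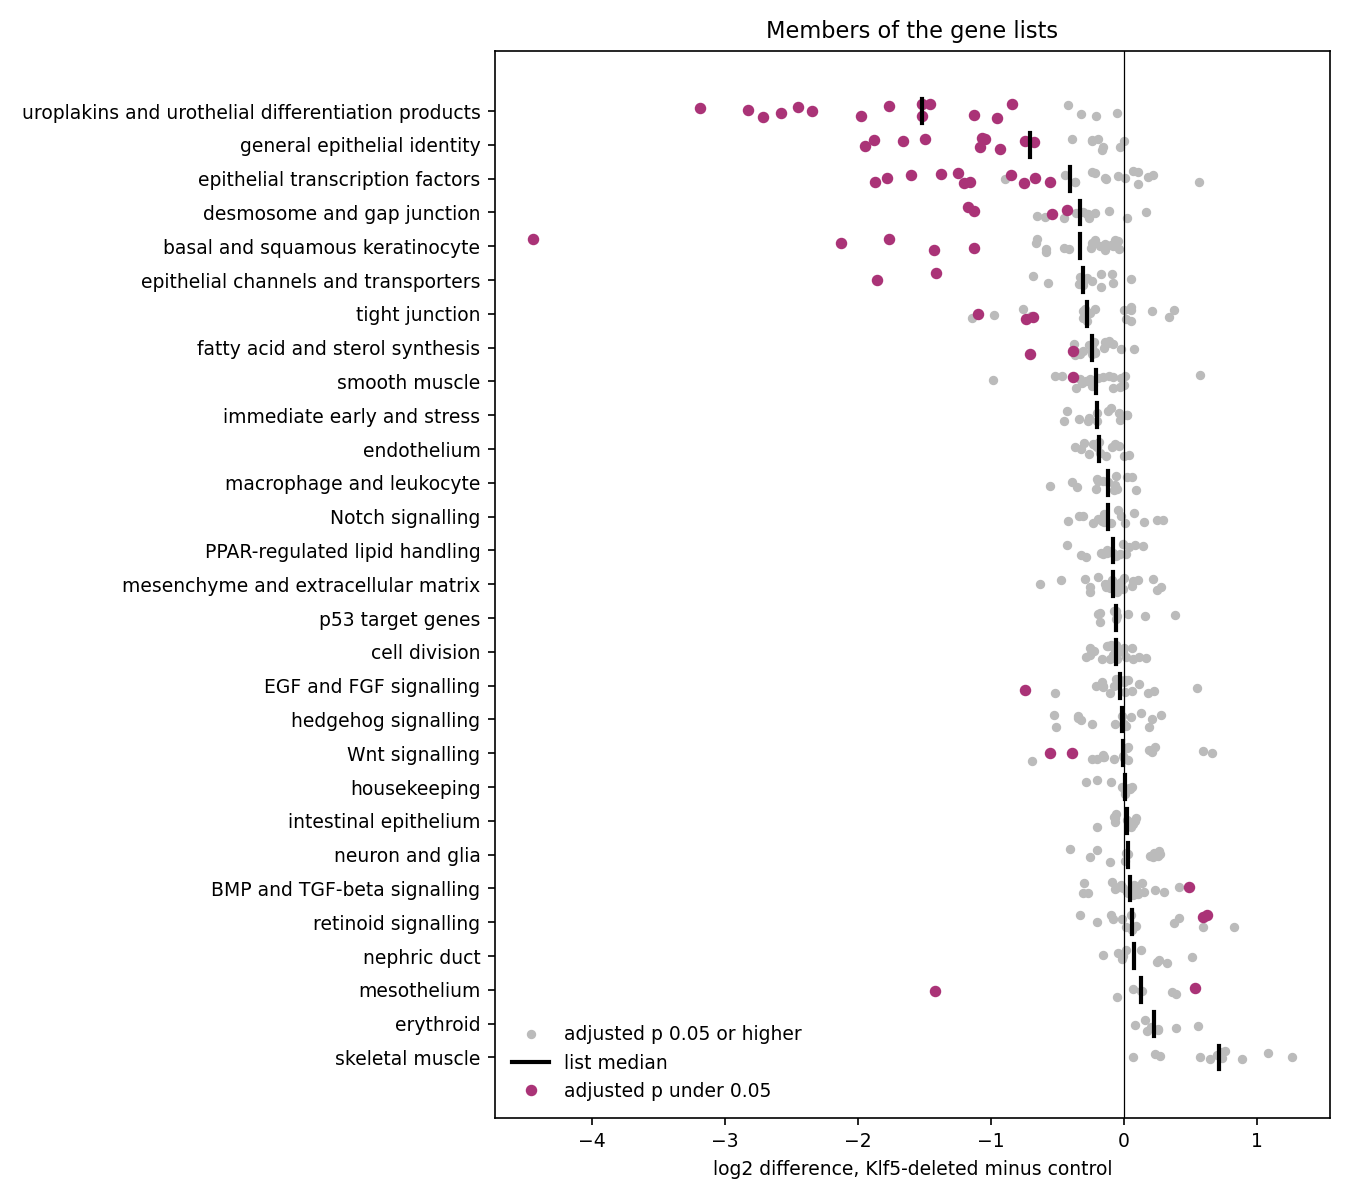
Log2 difference (Klf5-deleted minus control) of every measured member of the 29 tested lists, 1 point per gene, with black bars at the list medians and coloured points for genes past an adjusted p of 0.05. Lists are ordered by median, from uroplakins at -1.52 to skeletal muscle at 0.717, where no member passed the threshold.

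In the lipid lists 2 genes passed the threshold. Of 21 genes of fatty acid and sterol synthesis 2 fell, or 10 adjusted over the list alone: the desaturase gene Scd1 fell by 0.71 and the elongase gene Elovl6 fell by 0.38. The median was -0.238, or -0.0259 with arrays centred on housekeeping genes, and camera's adjusted p was 2.86e-08, against an adjusted p of 0.134 with an estimated correlation. Neither gene passed without Klf5-deleted 1, 2 or 3 or without control 1 or 2, and only 1 did without control 3. None of 15 genes of lipid handling regulated by PPAR receptors passed the threshold, also when adjusted over the list alone, and camera's adjusted p was 0.208, or 0.0424 without control 3, against an adjusted p of 0.569 over all arrays with an estimated correlation; Plin2 and Cpt1a differed by 0.04 and 0.15. Of these 15 genes 11 were lower and 4 higher, with a median of -0.0825.

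In the signalling lists few members passed. In the retinoid list 2 of 15 members rose, or 5 adjusted over the list alone: Aldh1a2, which makes retinoic acid, rose by 0.63 (SE 0.09) and the retinoic acid binding protein gene Crabp2 rose by 0.60 (SE 0.07). Camera's adjusted p was 0.00312, and an adjusted p of 0.112 with an estimated correlation; the array means of the list overlapped between groups. The overlap came from control 2 at 9.678, as controls 1 and 3 lay below every Klf5-deleted array. Rbp4, a member also placed in the later yolk sac list, read 11.06 on control 2 and 8.48 to 9.91 on the other arrays. How much of the overlap came from Rbp4 was not tested. Without control 2 the list median was 0.283, against 0.064 over all arrays. Of 19 Wnt genes Dkk3 fell by 0.56 and Wnt7b fell by 0.39, of 19 EGF and FGF genes Fgfr3 fell by 0.74, and of 20 BMP and TGF-beta genes Ltbp1 rose by 0.49. Camera's adjusted p for these lists was 0.564, 0.681 and 0.27. Adjusted over the list alone, 3 Wnt genes fell and 1 rose, 1 EGF or FGF gene fell and 1 rose, and 2 BMP or TGF-beta genes fell and 2 rose. No Wnt gene fell and no BMP or TGF-beta gene rose past the threshold in any fit that left out 1 array, Fgfr3 did not pass without Klf5-deleted 2 or control 1, and 1 retinoid gene rose past it without Klf5-deleted 1, Klf5-deleted 2, control 1 or control 3. No hedgehog or Notch gene passed among 15 and 16 members, with camera's adjusted p at 0.348 and 0.134, and 5 falls and 1 rise in the hedgehog list and 2 falls in the Notch list adjusted over the list alone. Shh, the ligand of the pathway whose promoter drives Cre, differed by -0.52 (SE 0.15, adjusted p = 0.168 by limma). Foxf1 and Smo of the hedgehog list differed by -0.07 and 0.02, and Notch2 and Rbpj of the Notch list by 0.08 and 0.01.

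Cell division and p53 target genes held no member past the threshold, among 24 and 10 measured. Camera's adjusted p was 0.0676 and 0.446, and the cell division list passed without Klf5-deleted 1 or 2, with adjusted p of 0.0312 and 0.0421, against an adjusted p of 0.264 over all arrays with an estimated correlation. In these lists 2 cell division genes fell and 1 p53 target rose when adjusted over the list alone. Pcna and Ccna2 differed by 0.11 and -0.09, and Ccng1 and Sesn1 by -0.06 and 0.16. Of 13 immediate early and stress genes none passed over all genes and 2 fell adjusted over the list alone; Jun and Dusp1 differed by -0.03 and -0.12, and the list median was -0.201, or 0.0109 with arrays centred on housekeeping genes, with camera's adjusted p at 0.00307 and an adjusted p of 0.452 with an estimated correlation. None of 9 housekeeping genes passed, with Actb and Rplp0 at 0.01 each; the list's median was 0.00702 and its mean -0.0471, with camera's adjusted p at 0.68.

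In the lists for the other cell types of the bladder, 3 genes passed the threshold: Synpo2, Msln and Wt1. Of 22 smooth muscle genes Synpo2 fell by 0.38 and the others did not pass, with 4 falls adjusted over the list alone; Synpo2 did not pass in any fit that left out 1 array. Acta2 differed by -0.08 (SE 0.06) and Myh11 by -0.36 (SE 0.12), with adjusted p of 0.614 and 0.246 by limma. The median of the list was -0.212, or -0.000143 with arrays centred on housekeeping genes; camera's adjusted p was 7.9e-05, and an adjusted p of 0.452 with an estimated correlation. None of 23 mesenchymal, 15 endothelial, 15 leukocyte and 13 neuronal and glial genes passed over all genes. Their medians were -0.0794, -0.19, -0.12 and 0.0335, or 0.133, 0.0224, 0.092 and 0.246 with arrays centred on housekeeping genes and -0.0998, -0.22, 0.019 and 0.231 without control 2, and camera's adjusted p was 0.229, 0.00226, 0.131 and 0.809; for endothelium it was an adjusted p of 0.452 with an estimated correlation, and an adjusted p of 0.14 with the preset one without Klf5-deleted 3. The leukocyte list passed without control 3, with an adjusted p of 0.000476; over all arrays its estimated correlation was 0.481, with an adjusted p of 0.705. Vim and Fn1 differed by -0.09 and 0.00, Cdh5 and Emcn by -0.20 and 0.00, C1qb and Lyz2 by -0.15 and -0.56, and Ednrb and Fabp7 by -0.40 and -0.20. Among 8 mesothelial genes Msln fell by 1.42 and Wt1 rose by 0.54, with a list median of 0.132, or 0.344 with that centring, a mean of 0.0199 and camera's adjusted p at 0.229, or 0.0491 without control 1, against an adjusted p of 0.452 over all arrays with an estimated correlation; Wt1 passed in the fit without control 2 and in no other that left out 1 array.

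Lists for tissues next to the bladder had no member past the threshold. The 12 skeletal muscle genes were all higher, with a median of 0.717 and camera's adjusted p at 6.79e-05, against an adjusted p of 0.452 with an estimated correlation; Acta1 and Actc1 differed by 0.23 and 0.27 (SE 0.29 and 0.26). The 8 erythroid genes had a median of 0.229, or 0.692 without control 2, and camera's adjusted p of 0.208, with Hbb-y and Hba-x at 0.25 and 0.40. The 10 nephric duct genes had a median of 0.0735, or 0.199 without control 2, and camera's adjusted p of 0.0613, with Gfra1 and Tfcp2l1 at 0.33 and -0.16. The 11 intestinal genes had a median of 0.0256, or -0.00757 without control 2, and a mean of -0.00949, with camera's adjusted p at 0.77 and Cdx1 and Apob at 0.03 and 0.09. Without control 2 the erythroid, nephric duct and neuronal lists passed camera's threshold, with adjusted p of 3.17e-05, 0.0012 and 0.0127, and the nephric duct list also passed without Klf5-deleted 1, with 0.0137. Over all arrays the estimated correlations of these 3 lists were 0.867, 0.337 and 0.535, with adjusted p of 0.705, 0.517 and 0.93.

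The arrays also differed within groups; Tpbpa, Uty and Kdm5d were chosen after their values were seen. The placental transcript Tpbpa read 13.13 on control 2 and between 6.18 and 10.34 on the other 5 arrays. On control 2, 44 genes were at least 4-fold higher than on every other array, and no other array had such a gene. That count cannot show transcripts high on several arrays, such as the granzyme genes on Klf5-deleted 1, Klf5-deleted 2 and control 2 described further on. Transcripts of the Y chromosome were low on control 1, where Uty read 5.05 against 8.38 to 9.59 elsewhere, and Xist was low on Klf5-deleted 3, at 8.38 against 11.47 to 12.54 elsewhere. Both groups overlapped in Xist, Eif2s3y, Kdm5d and Uty.

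**Figure D4:**
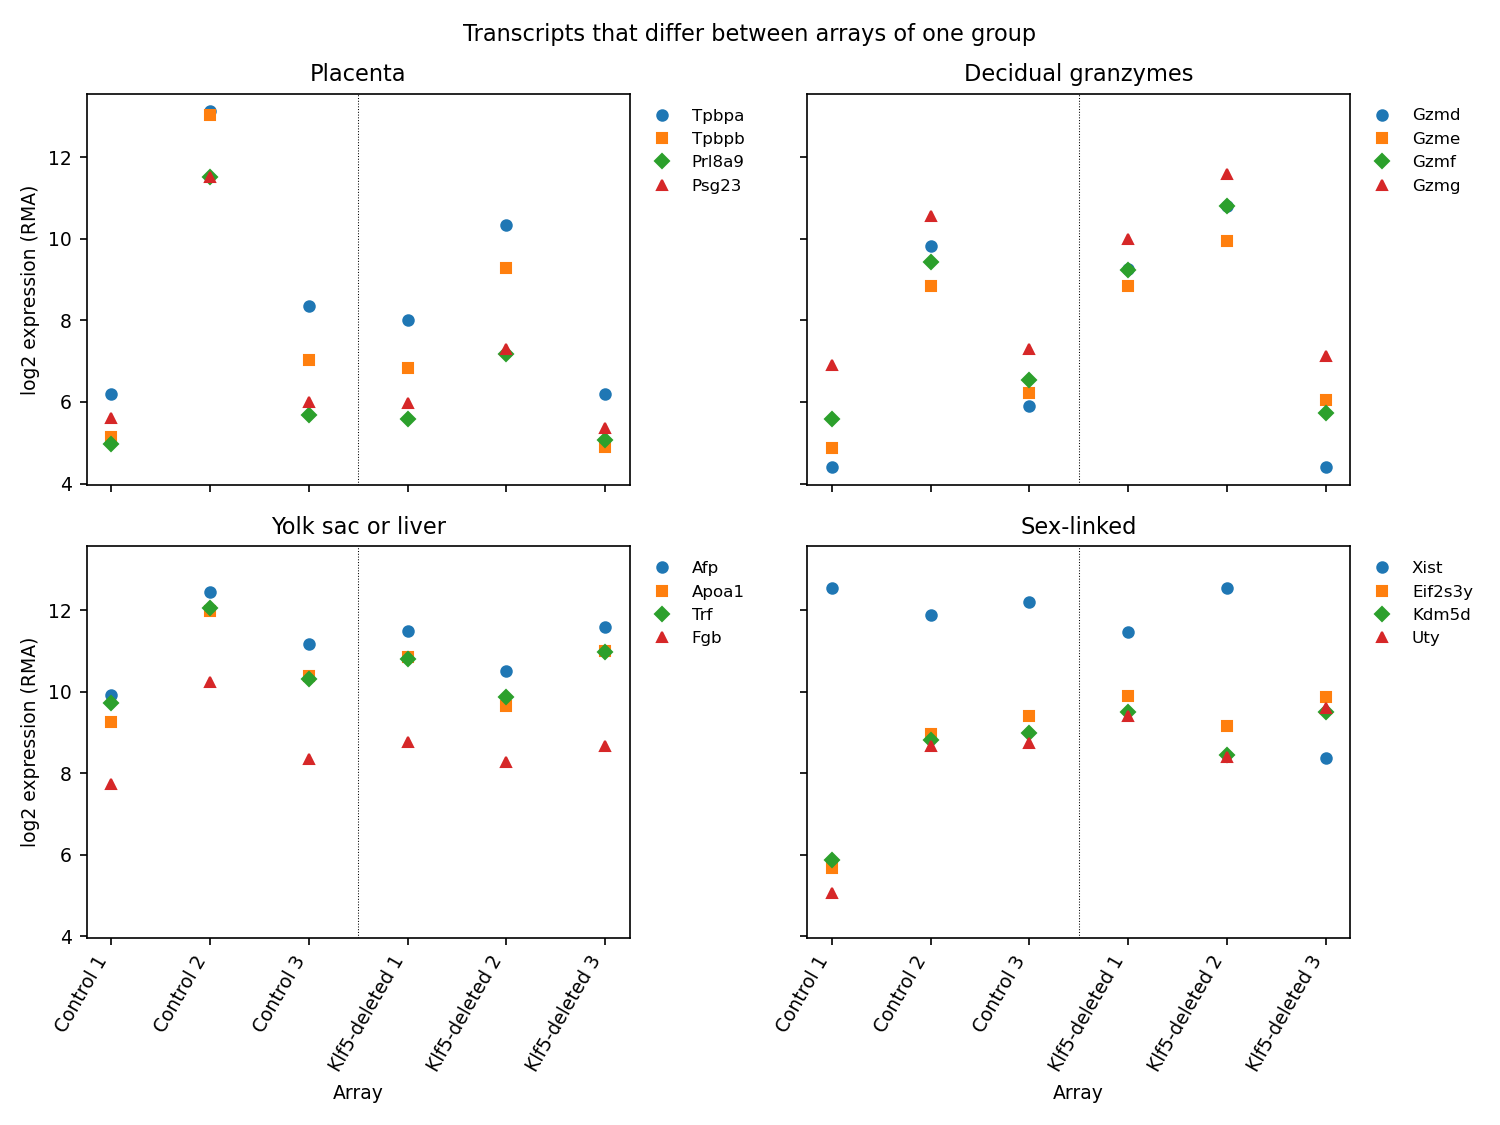
Log2 expression (RMA) of placental, granzyme, yolk sac or liver, and sex-linked genes on each of 6 arrays; each point is 1 gene on 1 array and the dotted line parts the groups. Tpbpa reads 13.13 on control 2, and Uty reads 5.05 on control 1.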

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

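The tests of an epithelial share as the sole change, with its interval counts and background subtraction, were chosen after the values were seen. So were the tests of placental RNA, of a sample other than bladder and of muscle. The other tests were fixed before.

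Among the features that carry no single gene name and were left out of the main comparison, 23 of 13768 passed an adjusted p of 0.05 in limma's fit over all features. Of these, 10 were lower and 13 higher in Klf5-deleted bladders. This was flagged as a difference in data outside the main measurement. What these features measure is not known here, and control features of the array were not told apart from unnamed transcripts. The probe set 10460253 fell by 3.19 on the log2 scale, and the largest rise was 0.806, for 10341433. Some of the higher features were dim, such as 10339626 with a mean log2 level of 4.568.

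The fall of urothelial genes was set against explanations other than an effect of Klf5 on transcription. The pools differed in sex makeup, and the sex-linked genes had a median difference of 1.44, with Xist at -1.41 and Eif2s3y at 1.63. None of the 4 passed, and the groups overlapped in 4 of 4, which argues against sex as what separated the groups. A smaller contribution was not excluded. Of 29 genes within 10 Mb of Klf5, 0% passed against 1.98% of 19826 elsewhere (Fisher's exact test, two-sided, p = 1; odds ratio 0, 95% interval up to 6.74), too few genes to exclude sequence carried along with the targeted locus, although none of the other called genes with a position lay there. A lower share of epithelial cells stays open: the general epithelial list had a median of -0.709, and the uroplakin list fell below it by a further -0.812 (permutation p = 0.0421), but in a check added after that p was seen, over members above the median level of all genes, the gap was -0.533 (permutation p = 0.285). The uroplakin list also holds the keratin genes Krt7, Krt8, Krt18 and Krt19, and its median over all members was the value of Krt18. Its uroplakin genes differed by -3.19 (Upk2) to -0.32 (Upk3b), so the gap of the medians is not one of uroplakins alone. The 95% interval of 14 of 18 general epithelial genes, and of 8 of the 12 above the median level, lay above the uroplakin median, which argues against an equal fall of all genes of these lists. The median was treated as known. Some members of the uroplakin list itself also lay above it, such as Upk3bl (-1.29 to -0.96), while others, such as Krt19 (-1.84 to -1.07), did not. The count therefore does not by itself separate the lists. A background of 5.055 to 5.869 was assumed, from the levels of Y-linked genes on control 1. After its subtraction the count of general epithelial genes was 7 of 12, and 5 of 12 at an assumed 8. The compression of dim features by RMA was not measured and stays open. General epithelial genes that other cells of the whole bladder, such as mesothelium, also express would fall less under a lower share, and RNA of whole bladders does not part these sources, so for such genes a lower share and lower transcription per cell cannot be told apart. The real grouping gave 395 genes and the highest of the other splits 0, 1 of 10 splits reaching the real count, and 10 splits are too few for a share under 0.05.

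Control 2 carried transcripts of placenta. The genes that defined this pattern, chosen after their values were seen, include Tpbpa, Tpbpb, Prl8a9 and Psg23, at 13.13, 13.03, 11.52 and 11.52, so the test used the 13 measured trophoblast markers that did not define it. Their median excess on control 2 over the other 5 arrays was 0.642, above all of 10000 random lists of matched level. The same value on the other arrays ran from -0.247 to 0.0682, and on Klf5-deleted 3 it lay below all random lists, so these lists understate the spread between arrays; 3 of the 13 are epithelial genes that fell with Klf5, and without them the median was 0.573. Klf5-deleted 2 also carried some of these transcripts, with Tpbpa at 10.34 and Tpbpb at 9.295, while the 13 markers had an excess of 0.0284 there. RNA of placenta in the pool is a candidate explanation for control 2, and the uroplakin list on control 2 deviated by -0.326 from the other controls in the median of its 19 members, which argues against a sample other than bladder. No biological explanation was tested.

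All 12 skeletal muscle genes were higher in Klf5-deleted bladders and none passed the threshold; camera called the list with the preset correlation and not with an estimated one (adjusted p = 0.452). Its residuals correlated between genes at 0.838 and the array means of the groups overlapped; control 2 lay at 9.34, above Klf5-deleted 1. The overlap came from control 2 alone, as controls 1 and 3 lay at 8.445 and 8.678, below every Klf5-deleted array. Without control 2 the list median was 0.906. Different amounts of attached striated muscle may account for the higher muscle genes, and an effect of genotype was not excluded.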

How the results depend on the processing

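The setting without control 2 and Klf5-deleted 2 was chosen after seeing the data; all others were fixed before. No gene of the 395 changed sign in any refit of the genes. Since the groups did not overlap for any of the 395, leaving out or weighting arrays could not change a sign. The block, the variance model and the filter on dim genes leave the difference of a gene as it was. Only a renewed quantile normalization and the choice among features could have changed a sign. The shift from centring on housekeeping genes was too small to reverse a difference past the threshold. Leaving out 1 array gave 141 to 349 genes (124 to 285 falls, 17 to 64 rises), 82 to 125 genes at 2-fold, 12 to 16 lists, and Klf5 differences of -0.68 to -0.51. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at 0.00915, 0.0313 and 0.0787; arrays numbered 2 and 3 matched best with their own number and those numbered 1 did not. With the number as a replicate block limma gave 110 genes (105 falls, 5 rises), 68 at 2-fold, and Klf5 at -0.5859 with an adjusted p of 0.137. Centring on housekeeping genes gave 1633 genes (261 falls, 1372 rises), Klf5 at -0.3738 with an adjusted p of 0.0651, and moved the median of all genes to 0.202; the array median of this list was the level of a single gene, B2m or Pgk1. Adjusted p of Klf5 over all settings ran from 0.0167 to 0.156. Genes above the median level numbered 239 (171 falls, 55 at 2-fold), all features 218 (175 falls, 43 rises), an adjusted p of 0.10 gave 735 (516 falls, 219 rises) and of 0.01 gave 133 (122 falls, 11 rises), and 1.5-fold in place of 2-fold gave 262. These settings differ by construction in the genes, arrays or thresholds used. The block left the difference of every gene as it was and changed only its spread and degrees of freedom. The housekeeping setting moved every difference by the same amount, while the housekeeping list itself had a median difference of 0.00702. The shift towards rises thus follows from the array levels of B2m and Pgk1. Why these levels differed between arrays was not tested. Without control 2 and Klf5-deleted 2 there were 312 genes, of which 223 were among the 395. With an estimated correlation camera called 0 of 29 lists (8 at an unadjusted p under 0.05), against 13 with the preset one and 9 with fry's directional test. The desmosome and gap junction, channel and retinoid lists had estimated correlations of 0.0017, 0.00823 and -0.0133, below the preset 0.01. A higher correlation between members is therefore not what removed the calls of these lists. Relative to the general epithelial list the medians changed sign for epithelial transcription factors (0.3049), tight junction (0.4325), desmosome and gap junction (0.3763), basal (0.3785) and channel genes (0.4059); the median of that list was subtracted from each, and no test of the differences was made. Of 852 values of the 58 other called named genes, 150 no longer passed. Of these values 0 had the opposite sign, which most settings could not have given for a called gene. Of 537 values of 36 uncalled genes 2 passed, and 44 values of named genes changed sign, all of uncalled genes. No gene was in more than 1 of the 30 lists fixed before, so the setting without shared members was not run. Signal over background was not analysed here.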

Other observations

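The lists of ceramide metabolism and vesicle trafficking were put together after the called genes had been seen, so no enrichment test is given for them. Of 41 measured ceramide and sphingolipid genes, 8 fell and none rose by limma. Fa2h, a fatty acid hydroxylase, fell by 2.48 (SE 0.24), Sptssb, a subunit of serine palmitoyltransferase, fell by 2.08 (SE 0.27) and the ceramide synthase gene Cers3 fell by 1.98 (SE 0.19). Of 29 apical vesicle trafficking genes, 10 fell and none rose. Besides Mal, Snx31 and Rab25, Rab27b, a GTPase of secretory vesicles, fell by 1.95 (SE 0.16), and the myosin genes Myo5b and Myo5c fell by 0.67 and 0.68.

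All 249 groups of genes that share a symbol stem and have 10 to 400 measured members were tested in both directions with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 498 tests. This was chosen after the data were seen. Fisher's test treats genes as independent, though genes of the same cells can vary together, so its p-values and intervals do not measure the spread between pools. By this test Aldh genes did not pass among falls, with 3 of 21 and an adjusted p of 0.43. Keratins were over-represented among falls, with 7 of 52 (odds ratio 9.79, 95% interval 3.69 to 22.1, adjusted p = 0.00886); Krt8, Krt18, Krt7 and Krt19, keratins of simple epithelia, fell by 1.77, 1.52, 1.51 and 1.46. Genes with the stem St were over-represented among rises, with 3 of 25 (odds ratio 36.5, 95% interval 6.85 to 126, adjusted p = 0.0299). These 3 code for sialyltransferases: St6gal2, St8sia1 and St8sia4 rose by 0.91, 0.55 and 0.55. Sialyltransferase genes did not all rise: among falls the stem held 2 of 25 (adjusted p = 1), St14, a protease gene, and St6galnac2, a sialyltransferase gene that fell by 0.93.

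The genes named next were chosen after their values were seen. Granzyme genes of the cluster Gzmd to Gzmg were high on Klf5-deleted 2, Klf5-deleted 1 and control 2. Gzmg read 11.58, 10.01 and 10.57 there, and 7.12 or less on Klf5-deleted 3 and control 1. Afp, a product of yolk sac and fetal liver, read 12.45 on control 2 and 9.93 on control 1, with the other 4 arrays between.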
